A study of Mus musculus with 8 samples.

How the data were processed

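Gene expression was measured on Illumina MouseRef-8 v2.0 bead arrays in 8 samples of basal keratinocytes sorted from mouse back skin, 1 array per sample. Per the labels, each sample pooled 2 mice, RNA was extracted with Trizol and amplified and labelled with the NuGEN Ovation Pico kit, and the arrays were read with GenomeStudio 2010.3. The deposited matrix holds, per the file headers, a bead-averaged signal intensity for each probe and array, the standard error of that intensity over beads, the number of beads, and a detection p-value against the negative control beads. These intensities were neither background-corrected nor normalised between arrays by the authors. The deposited table of sample values is on a log2 scale, and each of its values equalled the log2 of the raw intensity within 5.5e-05, so it was used as an alternative only. No genome build is named in the sources used here, so genes are given by symbol without coordinates.

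The 25697 probes were joined to genes by the platform's Entrez identifiers and symbols. Of these, 23978 carried 1 symbol and 1719 carried none, and 23962 matched an Entrez entry of the reference gene table. Background was corrected and arrays were quantile normalised with neqc in limma 3.58.1 under R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 14252 probes, 13361 of them with a gene. For each of the resulting 9545 genes the probe with the highest mean over all arrays was used, and 2588 genes had more than 1 kept probe. Arrays give no counts, so the number of arrays limits the precision. The lowest log2 value that counted as detected was between 5.08 and 5.62, depending on the array. Where the probe used was detected on no array of the dimmer group, the fold is given as "at least", computed against the lowest detected value of each of that group's arrays, or the gene's own value where higher. Other folds are given as computed, also where the dimmer group lay near the detection limit. This applies to Gli1, Dab2 and Shisa2, with means of 5.132, 5.057 and 5.245 in IFE cells.

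Groups followed the sort: Gli1+ (GFP-positive, 2 arrays), CD34+ (GFP-negative and CD34-positive, 3 arrays) and IFE (GFP-negative and CD34-negative, 3 arrays). All 8 arrays were fitted together with limma (lmFit and eBayes, 5 residual and 4.84 prior degrees of freedom), with 1 mean per group and a spread shared by the groups. The 3 pairwise comparisons were tested two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison. An adjusted p under 0.05 is called past the threshold. Errors of log2 differences are standard errors (SE) from this fit.

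Before the data were examined, the comparisons, 25 gene lists, the rule for naming genes and all alternatives below were fixed. The lists were hedgehog targets, hedgehog ligands, receptors and transducers, bulge stem cell, hair germ and matrix, isthmus and infundibulum, sebaceous gland, interfollicular basal, epidermal differentiation, hair shaft and root sheath keratins, basement membrane and hemidesmosome, neurotrophins and axon guidance ligands, Wnt pathway, BMP and TGF-beta pathway, Notch pathway, cell cycle, immediate early and dissociation stress, Merkel cell, melanocyte, fibroblast and dermal papilla, endothelial, Langerhans cell and macrophage, T cell, Schwann cell and nerve, skeletal muscle and adipocyte, and red blood cell. The 20 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The other 5 lists were too small to test. The adjusted p also rose where the estimate was under 0.01, as for bulge stem cell (-0.008) and cell cycle genes (0.001). A higher adjusted p with the estimate is therefore not by itself evidence that genes co-vary. Members are counted as past the threshold over all genes tested and, where given, adjusted over the list alone.

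The genes named in the text were chosen by that rule. It takes Gli1, Cd34, Itga6, Ptch1 and Hhip wherever measured. It adds, per comparison, the 8 characterised genes with the largest difference in each direction among those past the threshold whose groups did not overlap. It also adds up to 4 members of each list that passed the threshold, or up to 2 as values where none passed. Genes named outside the rule are marked as chosen after their values were seen.

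Samples of the 3 groups with the same replicate number come from the same pool of mice by design. Across genes, the correlation of deviations from the group means between samples of the same number ranged from -0.031 to 0.091. A fit with the replicate number as a block was run as an alternative, and its value is printed where it changes a call. The other alternatives were normexp with an offset of 50, no background correction, median centring, cyclic loess, the deposited log2 values, no detection filter, a detection p under 0.01 on every array of at least 1 group, the mean of a gene's probes, array weights (statmod 1.5.0), a mean-variance trend with robust eBayes, a fit to only the groups compared, and leaving out each array of the groups compared in turn. A block for slides was not run, since no slides are given in the sources used here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

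The pipeline was tested on simulated data of 9545 genes, of which 200 were changed. The 22 measured BMP and TGF-beta pathway genes were also raised 2-fold and are not counted as unchanged. The percentages come from draws that were not repeated, and the share of unchanged genes depends on how many genes were changed. With the same spread in every group, 4-fold changes were recovered for 79.1% of changed genes in Gli1+ versus CD34+, 76.1% in Gli1+ versus IFE and 76.1% in CD34+ versus IFE, and recovery of 2-fold changes was 1.49%, 5.97% and 4.48%. Unchanged genes made up 2.44%, 5.6% and 5.51% of the calls. With the spread of each group as measured, unchanged genes made up 29.3%, 26.2% and 1.55% of the calls, in the same order. Under that spread the threshold of 0.05 is therefore not met in the comparisons that use the Gli1+ arrays. With array weights, 5 of 100, 7 of 90 and 15 of 176 calls were on unchanged genes, in the same order. The weights also lowered recovery of 4-fold changes in the Gli1+ comparisons, from 57 to 33 and from 40 to 24 of 67 genes. On the real arrays the weighted fit called 1, 3 and 887 genes.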

Results

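The series profiles hedgehog-responding keratinocytes of resting (telogen) mouse back skin. The mice carried an eGFP reporter at Gli1, a transcription factor that is both an effector and a target of hedgehog signalling. Viable basal cells, recognised by α6 integrin on their surface, were sorted into GFP-positive cells (Gli1+, 2 arrays), GFP-negative cells with the bulge marker CD34 (CD34+, 3 arrays) and GFP-negative cells without it (IFE, interfollicular epidermis, 3 arrays). RNA of the Gli1+ cells of replicate 1 was, per the labels, not good enough for an array. The number of probes detected was 11188 and 9925 on the Gli1+ arrays of replicates 2 and 3, 12209 to 12601 on the CD34+ arrays and 11027 to 11680 on the IFE arrays. Raw median intensity lay between 117.9 and 129.1 on every array.

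The Gli1+ arrays resembled each other less than the replicates of the other groups did. Across genes, which are not independent replicates, their correlation was 0.82, against 0.933 to 0.945 among CD34+ arrays and 0.943 to 0.95 among IFE arrays. Gli1+ replicate 2 correlated at 0.873 to 0.887 with the CD34+ and IFE arrays, more than with Gli1+ replicate 3. Gli1+ replicate 3 correlated at 0.821 to 0.839 with the CD34+ and IFE arrays. Gli1+ replicate 3 lacked 946 probes that were detected on all 7 other arrays, Gli1+ replicate 2 lacked 245, and the 6 others lacked 34 to 172.

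**Figure D1:**
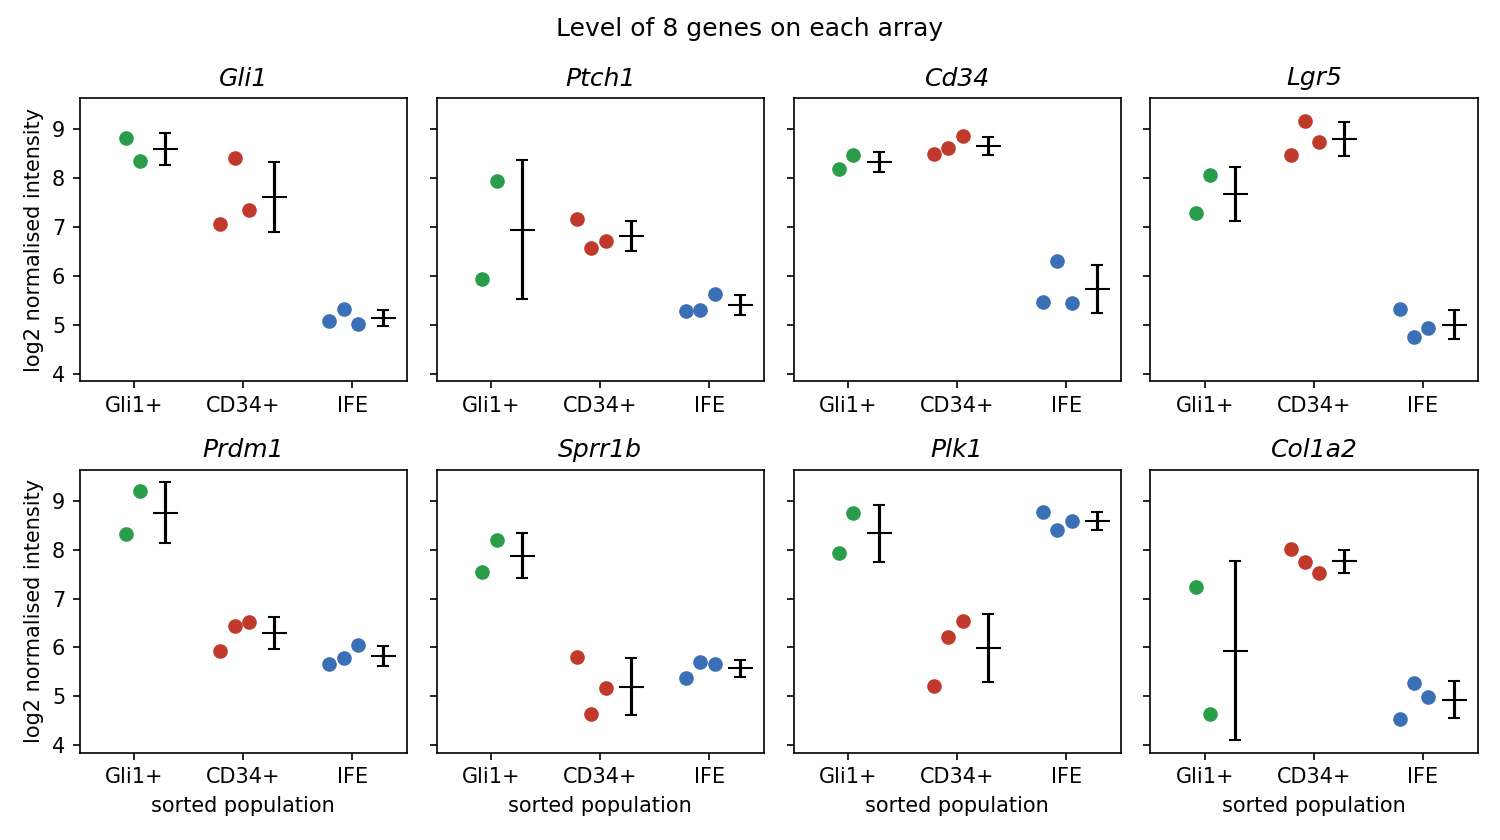
Log2 normalised intensity (vertical axis) of 8 genes on each array, by sorted population (horizontal axis). Points are arrays and bars show the mean and SD of a population. Gli1 was near the detection limit in IFE cells only, at 5.01 to 5.32, while Prdm1 and Sprr1b were highest on both Gli1+ arrays.

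CD34+ cells were compared with IFE cells to ask what separates bulge cells from the remaining GFP-negative basal cells. CD34+ cells had more RNA of bulge stem cell genes and of the 3 measured fibroblast and dermal papilla genes, and less of cell cycle genes. BMP and TGF-beta pathway genes were higher and epidermal differentiation genes lower as lists, with adjusted p = 0.121 and 0.282 with an estimated correlation. Cd34, the gene of the sorted surface protein, was 7.58-fold higher (log2 difference 2.92 ± 0.31 SE, n = 3 and 3, limma adjusted p = 0.000799). Of 21 measured bulge stem cell genes, 13 were higher (17 adjusted over the list alone) and 8 were not past the threshold, and the list as a whole was higher (camera adjusted p = 2.17e-22, and 0.00214 with an estimated correlation). Lgr5, an R-spondin receptor that marks hair follicle stem cells, was at least 11.5-fold higher (log2 3.80 ± 0.33, adjusted p = 0.000307). The Wnt receptor Fzd2 rose by 3.78 ± 0.29 on the log2 scale, the secreted protein Dkk3 by 3.70 ± 0.35 and the matrix protein periostin (Postn) by 3.21 ± 0.29.

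The largest increases in CD34+ cells were in Hoxd8, a homeobox gene (28.3-fold, log2 4.82 ± 0.43), the endocytic adaptor Dab2 (25.1-fold) and Shisa2, an inhibitor of Wnt and FGF receptor maturation (24.8-fold). Sgcd, a sarcoglycan, was 21.1-fold higher, Angptl7 21.1-fold and Igdcc4 18.5-fold. The peptide hormone gene Cck was at least 12.4-fold and Il31ra, a receptor subunit for the itch cytokine interleukin 31, at least 16.8-fold higher. The other kept probe of Dab2 gave a smaller difference of 2.83, and that of Sgcd 2.08.

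Of 22 BMP and TGF-beta pathway genes, 7 were higher (8 adjusted over the list alone) and 15 were not past the threshold. Fstl1, a secreted glycoprotein, rose by 4.04 ± 0.36, Ccn2, a target of TGF-beta, by 3.65 ± 0.29, the BMP antagonist Grem1 by 3.32 ± 0.30 and Id2, a BMP target, by 2.94 ± 0.46. The list was higher at camera adjusted p = 6.28e-05, with adjusted p = 0.121 with an estimated correlation. Hair germ and matrix genes were higher as a list (camera adjusted p = 0.00225, adjusted p = 0.184 with an estimated correlation, and 0.157 without the detection filter, within a range from 0.000888), through 2 of 6 members (3 adjusted over the list alone), the homeobox genes Hoxc13 (2.98 ± 0.43) and Dlx3 (2.57 ± 0.28). In the list of hair shaft and root sheath keratins, Krt6b (3.19 ± 0.40) and Krt6a (3.01 ± 0.53), keratins of the companion layer and of stressed epidermis, were higher, Gata3 was lower (-1.63 ± 0.31) and 1 gene did not pass. Adjusted over the list alone, 3 were higher and 1 lower. That list's camera adjusted p was 0.0461, and adjusted p = 0.184 with an estimated correlation, 0.0628 with the replicate block, and between 0.0324 and 0.2 over the alternatives. It was also lost without CD34+ replicate 2 (0.0628) or 3 (0.0706) and without IFE replicate 1 (0.0574), 2 (0.079) or 3 (0.0542).

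Wnt pathway genes split, with 6 higher, 3 lower and 13 not past the threshold (7 higher and 9 lower adjusted over the list alone). Beside Fzd2 and Dkk3, Wnt5a, a ligand of non-canonical signalling, was lower by -2.47 ± 0.44, and the receptor Fzd10 by -2.24 ± 0.40, although its other probe gave 0.52. The list's median was -0.29 while its mean was 0.14 and the test pointed upward (camera adjusted p = 0.881). Among neurotrophins and axon guidance ligands, Sema3e (3.12 ± 0.31) and Bdnf (1.80 ± 0.43, at least 2.53-fold) were higher and Sema3d (-2.07 ± 0.27) and Sema3f (-2.02 ± 0.42) lower, with 10 not past the threshold and camera adjusted p = 0.466 (3 higher and 2 lower adjusted over the list alone). Bdnf missed the threshold with the replicate block (adjusted p = 0.0609) and without any 1 of the 6 CD34+ and IFE arrays, with 0.168 the highest value, without IFE replicate 3. It passed without Gli1+ replicate 2 (0.00385) or 3 (0.00238).

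Gli1 itself was 5.56-fold higher in the GFP-negative CD34+ cells than in IFE cells (log2 2.47 ± 0.37, adjusted p = 0.00477, higher on 3 of 3 arrays). Ptch1, the hedgehog receptor and a target of the pathway, differed by 1.42 ± 0.46 (adjusted p = 0.132). Of 7 hedgehog targets, Gli1 was higher, Cdk6, a G1 kinase, was lower (-1.84 ± 0.32) and 5 were not past the threshold (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.494). Of 6 hedgehog ligands, receptors and transducers, the co-receptor Gas1 was higher (1.61 ± 0.27), also adjusted over the list alone, and the list gave camera adjusted p = 0.0626, which became 0.0488 without IFE replicate 3 and ranged from 0.0409 to 0.272 over the alternatives. Cdk6 and Gas1 missed the threshold without IFE replicate 1 (adjusted p = 0.0534 and 0.0508) and without IFE replicate 3 (0.0589 and 0.0571). Itga6, the integrin of the sort, differed by -0.50 ± 0.27 (adjusted p = 0.401).

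Cell cycle genes were lower in CD34+ cells: 4 of 19 passed the threshold (7 adjusted over the list alone), the remaining 15 did not, and all 19 had a negative difference (camera adjusted p = 2.05e-07, and 0.0179 with an estimated correlation). The mitotic kinase Plk1 was 6.08-fold lower, the survivin gene Birc5 fell by 1.95 ± 0.37 and the centromeric histone Cenpa by 1.89 ± 0.41, while cyclin A2 (Ccna2) was 2.39-fold lower. The other probes of Birc5 gave -1.09 and -1.02, and it missed the threshold with the mean of its probes (limma adjusted p = 0.0668). With the replicate block the adjusted p was 0.057 for Cenpa and 0.089 for Ccna2. Epidermal differentiation genes were lower as a list (camera adjusted p = 0.000445, and adjusted p = 0.282 with an estimated correlation), with 2 of 24 past the threshold (7 adjusted over the list alone). These were the transcription factor Grhl1 (-1.63 ± 0.38) and the cornification protease Casp14 (-1.48 ± 0.31, adjusted p = 0.0594 with the replicate block). Interfollicular basal genes were also lower (camera adjusted p = 0.0403, and adjusted p = 0.184 with an estimated correlation), with 10 members not past the threshold over all genes and 2 lower adjusted over the list alone. Ly6d differed by -1.22 ± 0.34 and Fgfbp1 by -1.10 ± 0.31. That list's adjusted p ranged from 0.0151 to 0.108 over the alternatives and missed the threshold without CD34+ replicate 2 (0.0995) or 3 (0.0622) and without IFE replicate 1 (0.0574) or 2 (0.108). Of 11 isthmus and infundibulum genes, 3 were lower, also adjusted over the list alone: Gata6, a transcription factor of the duct and junctional zone (-2.02 ± 0.38), the defensin Defb6 (-1.33 ± 0.27) and Krt79 (2.38-fold lower, adjusted p = 0.0581 with the replicate block). The list gave camera adjusted p = 0.0626, and 0.0401 without IFE replicate 3.

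The largest decreases in CD34+ cells were in the glutamate transporter Slc1a1 (10.5-fold lower, log2 -3.39 ± 0.45), the inflammatory caspase Casp4 (7.55-fold), Tnfrsf19, a receptor of the TNF family (7.50-fold), the interleukin 18 receptor Il18r1 (7.36-fold), the complement regulator Cd55 (7.23-fold) and the spindle protein Aspm (6.49-fold). The transporter Slc2a9 was at least 5.71-fold and the G protein Gna14 at least 5.28-fold lower. The other probes of Slc1a1 and Tnfrsf19 gave -0.72 and -0.42. Notch1 was lower by -1.23 ± 0.27 (adjusted p = 0.0639 with the replicate block), the 1 called of 11 Notch pathway genes (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.49).

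Some markers of other cell types moved with the bulge genes and others did not. Of 12 fibroblast and dermal papilla genes on the array, 3 passed the detection filter. All 3 measured fibroblast and dermal papilla genes were higher in CD34+ cells, also adjusted over the list alone: the collagen genes Col6a1 (2.97 ± 0.29, at least 5.69-fold) and Col1a2 (2.83 ± 0.56) and Sparc (2.20 ± 0.35). The list gave camera adjusted p = 1.38e-05, and 0.0427 with an estimated correlation, but 0.0597 without the detection filter, within a range from 5.62e-06. Mitf, the melanocyte transcription factor, was 8.30-fold higher (3.05 ± 0.35), the 1 called of 4 melanocyte genes (2 adjusted over the list alone, camera adjusted p = 0.0626, and 0.0449 without CD34+ replicate 2). Langerhans cell and macrophage (camera adjusted p = 0.488), T cell (0.183), sebaceous gland (0.596), basement membrane and hemidesmosome (0.27) and immediate early and dissociation stress (0.135, and 0.0243 without CD34+ replicate 1) lists did not pass. Sebaceous gland genes had a median of -0.08 and a mean of 0.37, with the test pointing upward and 2 members higher adjusted over the list alone. Of these genes, Mgst1 differed by 1.62 ± 0.46 (limma adjusted p = 0.0841, and 0.0445 with the replicate block). Piezo2, the measured Merkel cell gene, differed by -0.32, the endothelial Egfl7 by -0.04, the glial genes Mbp and Ngfr by -1.52 and -1.42, and Hba-a1, a haemoglobin gene, by 0.59, none of them past the threshold, and no muscle or adipocyte gene was measured.

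In all, 458 of 9545 genes passed the threshold (281 higher and 177 lower in CD34+ cells), and 194 of them differed at least 4-fold. Every called gene had non-overlapping groups, as did 27.7% of all genes, where chance gives 10%. The count was 249, 216 and 254 without CD34+ replicates 1, 2 and 3, and 194, 217 and 189 without IFE replicates 1, 2 and 3, and 33 of the 53 named genes past the threshold stayed past it whichever array of the groups compared was left out. The other 20, Il18r1, Cd55, Cdk6, Gas1, Gata6, Defb6, Krt79, Grhl1, Casp14, Krt6a, Gata3, Sema3f, Bdnf, Wnt5a, Fzd10, Notch1, Birc5, Cenpa, Ccna2 and Col1a2, missed it without at least 1 of these arrays, at adjusted p between 0.0507 and 0.168. Median centring, under which the median of all genes was 0.126 in place of -0.014, gave 310 higher and 91 lower, and the deposited log2 values gave 306 and 83.

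**Figure D2:**
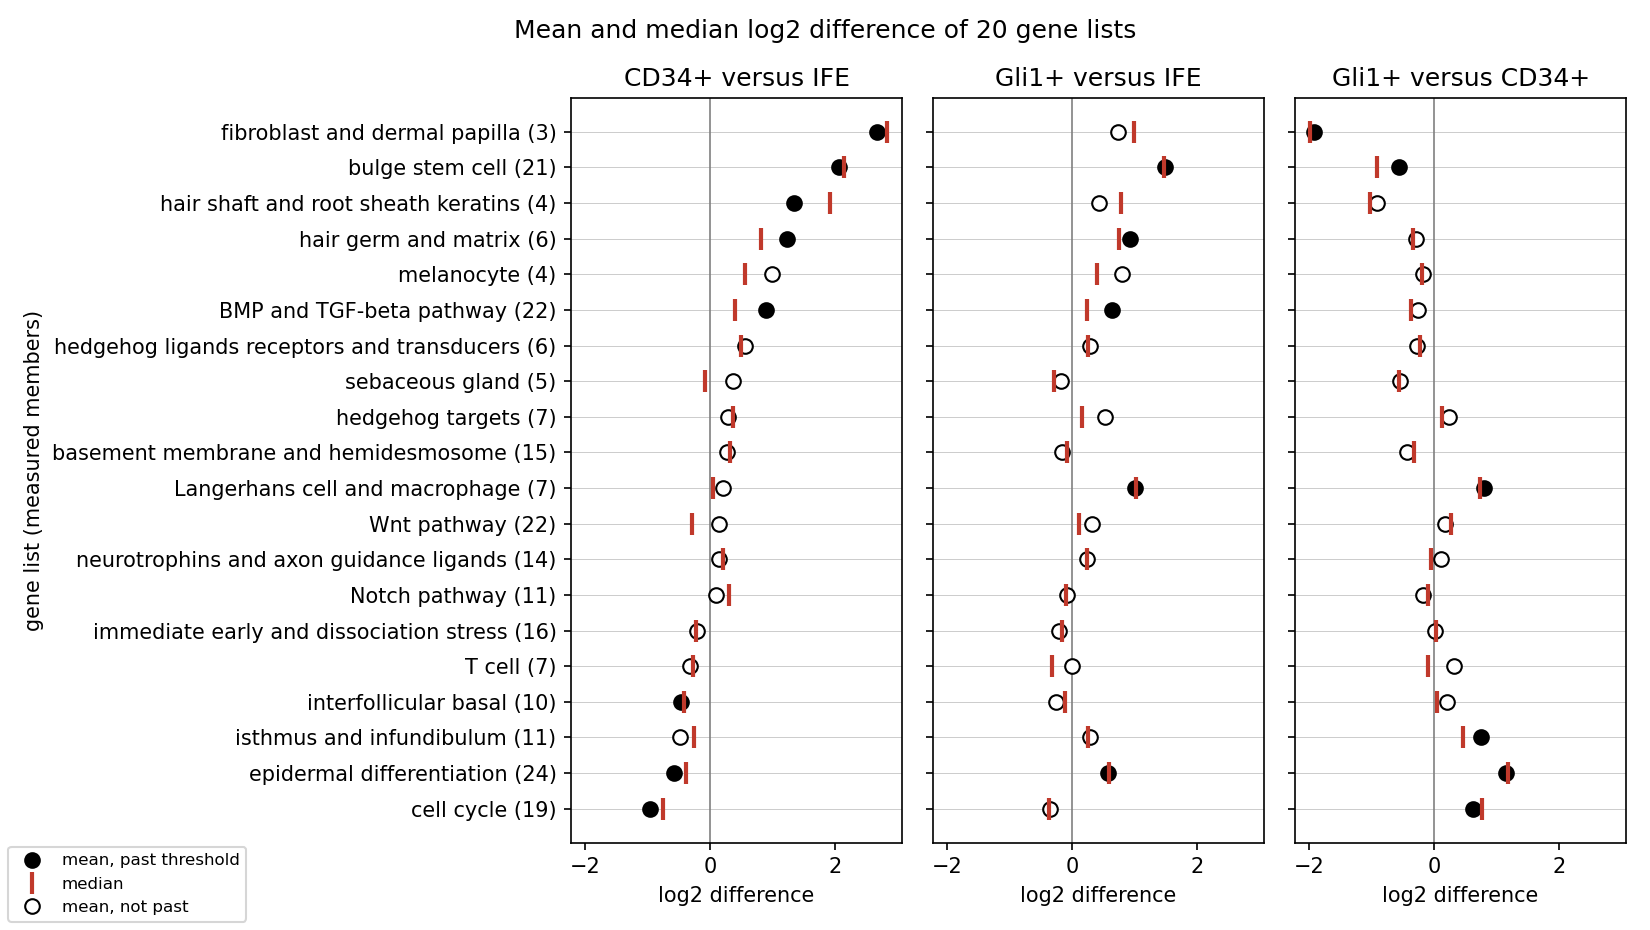
Mean (circles, filled where the camera test passed) and median (red bars) log2 difference on the horizontal axis, for the 20 tested gene lists on the vertical axis, in each comparison. Bulge stem cell genes had a mean of 2.06 in CD34+ versus IFE and 1.49 in Gli1+ versus IFE, and -0.57 in Gli1+ versus CD34+.

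Gli1+ cells were compared with IFE cells to ask what marks hedgehog-responding basal cells against the interfollicular fraction. Gli1+ cells had more Gli1 and more RNA of bulge stem cell genes. Gli1 was 11-fold higher (log2 3.46 ± 0.42, n = 2 and 3, limma adjusted p = 0.00751, higher on 2 of 2 arrays). Its IFE levels of 5.07, 5.32 and 5.01 lay near the detection limit, so the size of this fold is uncertain. Cd34 was 6.03-fold higher (2.59 ± 0.35, adjusted p = 0.00828), although the Gli1+ sort did not select on CD34. Of 21 bulge stem cell genes, 10 were higher (13 adjusted over the list alone), 11 were not past the threshold, and 20 had a positive difference (camera adjusted p = 3.27e-14, and 0.0065 with an estimated correlation).

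Among these bulge genes, the secreted Wnt inhibitor Wif1 was at least 10.7-fold higher (3.94 ± 0.50), tenascin C (Tnc), a matrix protein, 9.20-fold (3.20 ± 0.46, with 0.62 from 1 of its other probes) and Lgr5 at least 5.29-fold (2.68 ± 0.37). Hoxd8 (22.1-fold), Shisa2 (4.40 ± 0.36), Dab2 (17.2-fold, with a difference of 0.59 on its other probe), Apbb1, an adaptor of the amyloid precursor protein (16.5-fold), Fstl1 (14.4-fold) and the serpin Serpinb11 (11.6-fold) had the other largest increases. Of 22 BMP and TGF-beta pathway genes, 6 were higher and 16 were not past the threshold (8 higher and 1 lower adjusted over the list alone). They included Fstl1 (3.84 ± 0.40), Ccn2 (2.66 ± 0.32), Grem1 (2.52 ± 0.33) and the ligand Tgfb2 (2.25 ± 0.33). The list was higher at camera adjusted p = 0.00231, with adjusted p = 0.353 with an estimated correlation. Its adjusted p ranged from 0.00026 to 0.111 over the alternatives, the highest without Gli1+ replicate 2.

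Of 7 hedgehog targets, 2 were higher, Gli1 and the transcription factor Mycn (1.87 ± 0.30, at least 2.49-fold), 1 was lower, Cdk6 (-1.72 ± 0.35), and 4 were not past the threshold (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.287). Ptch1 differed by 1.54 ± 0.52 (adjusted p = 0.151). Its levels on the Gli1+ arrays were 5.93 and 7.95, and with replicate 3 as the lone Gli1+ array its adjusted p was 0.00476, against 0.469 with replicate 2 alone. The ligand, receptor and transducer list gave camera adjusted p = 0.287, with 6 members not past the threshold (1 higher adjusted over the list alone), of which Gas1 differed by 1.27 ± 0.31 and Smo by -0.44 ± 0.48. Itga6 differed by -0.75 ± 0.31 (adjusted p = 0.237). Hhip, a further target, was detected on no array.

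Prdm1, which encodes the repressor Blimp1, was 7.62-fold higher (2.93 ± 0.36), the 1 called of 11 isthmus and infundibulum genes, also adjusted over the list alone (camera adjusted p = 0.332). Sprr1b, a precursor of the cornified envelope, rose by 2.30 ± 0.39, the 1 called of 24 epidermal differentiation genes, also adjusted over the list alone. That list was higher at camera adjusted p = 0.00231, with adjusted p = 0.382 with an estimated correlation, and missed the threshold without Gli1+ replicate 3 (0.161, the highest of a range from 0.000341) and without IFE replicate 1 (0.0586). Hair germ and matrix genes were higher as a list (camera adjusted p = 0.0303, and adjusted p = 0.353 with an estimated correlation), through Dlx3 (1.98 ± 0.32) of 6 members (2 adjusted over the list alone). It ranged from 0.0101 to 0.4 over the alternatives, the highest without Gli1+ replicate 2, and gave 0.0863 without IFE replicate 2. Of 22 Wnt pathway genes, 3 were higher, Wif1, Dkk3 (2.43 ± 0.39) and Fzd2 (2.09 ± 0.32, at least 3.11-fold), and 1 lower, Wnt5a (-2.59 ± 0.49), with 18 not past the threshold (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.163). Sema3e rose by 1.90 ± 0.35, the 1 called of 14 neurotrophins and axon guidance ligands, also adjusted over the list alone (0.287).

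Genes lower in Gli1+ than in IFE cells included the EGF receptor ligand Epgn (8.76-fold, log2 -3.13 ± 0.62), Qrich1 (7.41-fold), the NF-kappa-B regulator Nfkbid (7.25-fold), the lipid transporter Mfsd2a (-2.81 ± 0.42), Phldb2 (6.96-fold), Casp4 (6.50-fold), the interleukin 36 receptor Il1rl2 (6.49-fold) and Dcaf5 (at least 3.86-fold). The cell cycle list did not pass (camera adjusted p = 0.163), with Cdc20 at -1.27 ± 0.54 and Mcm2 at -1.27 ± 0.36. Neither did the lists of Notch pathway (0.779), sebaceous gland (0.695), interfollicular basal (0.328), hair shaft and root sheath keratins (0.328), basement membrane and hemidesmosome (0.429) or immediate early and dissociation stress genes (0.287).

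Some markers of other cell types differed between these groups and others did not. All 7 Langerhans cell and macrophage genes had a positive difference, and the list was higher (camera adjusted p = 0.00231, with adjusted p = 0.353 with an estimated correlation). Its members were not past the threshold over all genes (3 higher adjusted over the list alone), with the MHC class II genes H2-Aa at 1.87 ± 0.48 and H2-Ab1 at 1.41 ± 0.32. Mitf was 5.24-fold higher (2.39 ± 0.39), the 1 called of 4 melanocyte genes, also adjusted over the list alone (camera adjusted p = 0.1, 0.0464 with the replicate block, 0.0344 without Gli1+ replicate 3, and up to 0.4 over the alternatives). Hba-a1 was at least 4.17-fold higher (2.35 ± 0.45). The fibroblast and dermal papilla list gave 0.163 (0.0435 without Gli1+ replicate 3, up to 0.595 over the alternatives, and 1 higher adjusted over the list alone), with Col1a2 at 1.00 ± 0.62, and the T cell list 0.695, with Cd3e at 1.29 ± 0.44. Piezo2 differed by 0.36, Egfl7 by -0.45, Ngfr by -0.67 and Mbp by -0.20.

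In all, 206 genes passed the threshold (124 higher and 82 lower in Gli1+ cells), 127 of them at least 4-fold apart, all with non-overlapping groups, as had 31.6% of all genes, where chance gives 20%. The count was 67 with the replicate block (which ended the calls of Epgn, Qrich1, Dcaf5, Mycn, Cdk6, Dlx3, Sprr1b, Sema3e, Mitf and Hba-a1, at adjusted p between 0.0536 and 0.128), 3 with array weights (Shisa2, Dab2 and Apbb1), 6 in a fit to only the groups compared, 42, 50 and 39 without IFE replicates 1, 2 and 3, and 1200 and 329 without Gli1+ replicates 2 and 3. Of the 33 named genes past the threshold, 15 stayed past it whichever IFE array was left out. These were Gli1, Cd34, Hoxd8, Shisa2, Dab2, Apbb1, Wif1, Fstl1, Serpinb11, Phldb2, Casp4, Tnc, Prdm1, Ccn2 and Grem1. The other 18 missed it without at least 1 IFE array, at limma adjusted p up to 0.163. Leaving out a Gli1+ array does not test stability, since the lone array is then assumed to vary like the other groups. With array weights 3 of the 33 stayed past the threshold, and with only the groups compared 5. Gli1 and Cd34 had limma adjusted p = 0.0645 and 0.0726 with array weights. In simulated data with the measured spread of each group 26.2% of such calls were on unchanged genes, and the split was 174 higher and 36 lower with median centring, 171 and 49 with cyclic loess and 158 and 12 with the deposited log2 values.

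Gli1+ cells were then compared with CD34+ cells, the GFP-negative bulge fraction. With the preset correlation of camera, the lists of epidermal differentiation, isthmus and infundibulum and cell cycle genes were higher in Gli1+ cells and those of bulge stem cell and fibroblast genes lower. The list of Langerhans cell and macrophage genes was also higher. None of these list calls held with an estimated correlation (camera adjusted p between 0.106 and 0.267). Of the Langerhans cell and macrophage list no gene passed, and of each of the other 5 lists 1 or 2 genes passed in its direction. For bulge stem cell and cell cycle genes the estimated correlation was -0.008 and 0.001, under the preset 0.01, so co-variation does not account for the loss. Gli1 differed by 0.98 ± 0.42 (adjusted p = 0.258), with levels of 8.82 and 8.36 on the Gli1+ arrays and 7.06, 8.42 and 7.35 on the CD34+ arrays. Cd34 differed by -0.33 ± 0.35 (adjusted p = 0.665), Ptch1 by 0.12 ± 0.52 (0.93) and Itga6 by -0.24 ± 0.31 (0.724).

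Of 24 epidermal differentiation genes, 22 had a positive difference, with a median of 1.17 (camera adjusted p = 5.79e-10, with adjusted p = 0.157 with an estimated correlation). Of these genes 2 passed the threshold over all genes (14 adjusted over the list alone), Sprr1b (6.39-fold, log2 2.68 ± 0.39, n = 2 and 3, limma adjusted p = 0.0225) and Casp14 (5.80-fold, 2.54 ± 0.34). Isthmus and infundibulum genes were higher as a list (camera adjusted p = 0.00171, with adjusted p = 0.141 with an estimated correlation), with Prdm1 5.52-fold higher (2.46 ± 0.36) and 10 not past the threshold (3 higher adjusted over the list alone). Cell cycle genes were higher as a list (camera adjusted p = 0.00171, with adjusted p = 0.106 with an estimated correlation), with Plk1 5.09-fold higher (2.35 ± 0.43) and 18 not past the threshold (4 higher adjusted over the list alone).

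Bulge stem cell genes were lower as a list, with a median of -0.92 (camera adjusted p = 0.00171, with adjusted p = 0.106 with an estimated correlation). Igfbp5, a binding protein of insulin-like growth factors, was lower by -1.93 ± 0.28 and Fzd2 by -1.69 ± 0.32, Tgfb2 was higher by 1.93 ± 0.33, and 18 did not pass (2 higher and 9 lower adjusted over the list alone). Tgfb2 was also the 1 called of 22 BMP and TGF-beta pathway genes (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.31), and Fzd2 the 1 called of 22 Wnt pathway genes (2 higher and 3 lower, 0.396). Mycn was 2.83-fold higher, the 1 called of 7 hedgehog targets, also adjusted over the list alone (0.372). Krt6b (-2.24 ± 0.45) was the 1 called of 4 hair shaft and root sheath keratins (2 lower adjusted over the list alone, 0.275) and the laminin gene Lamb3 (-1.46 ± 0.30) of 15 basement membrane and hemidesmosome genes (also adjusted over the list alone, 0.112, and 0.0266 without Gli1+ replicate 2, within a range from 0.0266 to 0.935). Sema3d (1.56 ± 0.30) was the 1 called of 14 neurotrophins and axon guidance ligands (1 higher and 1 lower adjusted over the list alone, 0.738, with a median of -0.05 against a mean of 0.10 and a test pointing upward).

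The other largest increases in Gli1+ cells were in the EGF family ligand Btc (10.1-fold, log2 3.33 ± 0.55), the lipase Lipn (at least 6.30-fold), Dnase1l2, a nuclease of cornifying cells (at least 6.07-fold), the secretoglobin Scgb1a1 (7.78-fold), Flvcr2 (7.15-fold), Actr5 (at least 5.76-fold), the late cornified envelope gene Lce1c (7.03-fold) and the cytokinesis gene Cep55 (at least 4.89-fold). Without Gli1+ replicates 2 and 3 in turn, the log2 difference was 3.9 and 1.74 for Actr5 and 3.88 and 1.71 for Lce1c. The other probes of Dnase1l2 gave -0.07 and 1.08. With 1 Gli1+ array left out a different probe of Dnase1l2 is the brightest and the difference is -0.14 without Gli1+ replicate 2 and -0.01 without replicate 3. The largest decreases were in the transcription factor Nfatc4 (at least 9.19-fold, log2 -3.97 ± 0.32, adjusted p = 0.00273), Jazf1 (13.2-fold), Niban1 (11.1-fold), Proser3 (at least 5.90-fold, with -0.70 on its other probe), the synuclein Sncg (8.77-fold, with -1.54 on its other probe), the mitochondrial protein Cisd1 (8.47-fold), Ddah2 (8.26-fold) and Rapgef3, a cAMP-activated exchange factor (8.15-fold). Some of these depended on the Gli1+ array kept. Without Gli1+ replicates 2 and 3 in turn, the log2 difference was -4.72 and -2.67 for Jazf1, -4.17 and -1.93 for Cisd1, and -4 and -1.98 for Rapgef3. The lists of hedgehog ligands, receptors and transducers (camera adjusted p = 0.527), hair germ and matrix (0.394), sebaceous gland (0.412, 1 higher and 2 lower adjusted over the list alone), interfollicular basal (0.396), Notch pathway (0.566, 1 lower adjusted over the list alone) and immediate early and dissociation stress genes (0.738) did not pass.

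Here too, some markers of other cell types differed and others did not. Of 3 fibroblast and dermal papilla genes, Sparc (-1.99 ± 0.39) and Col6a1 (-1.99 ± 0.33) were lower and 1 did not pass (3 lower adjusted over the list alone). The list gave camera adjusted p = 0.00161, with adjusted p = 0.106 with an estimated correlation, and 0.276 without the detection filter, the highest over its alternatives (the lowest was 0.000242). All 7 Langerhans cell and macrophage genes had a positive difference (camera adjusted p = 0.00516, with adjusted p = 0.267 with an estimated correlation). The list missed the threshold without Gli1+ replicate 3 (0.0747, within a range from 0.00239), and its members did not pass over all genes (1 higher adjusted over the list alone), with H2-Eb1 at 1.24 ± 0.50 and H2-Ab1 at 1.17 ± 0.32. The melanocyte (0.738) and T cell lists (0.542, median -0.10 against a mean of 0.32, a test pointing upward and 1 higher adjusted over the list alone) did not pass. Hba-a1 differed by 1.77, Mbp by 1.32, Ngfr by 0.76, Piezo2 by 0.68 and Egfl7 by -0.41.

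In all, 136 genes passed the threshold (55 higher and 81 lower in Gli1+ cells), 69 of them at least 4-fold apart, all with non-overlapping groups, as had 31.4% of all genes, where chance gives 20%. With the replicate block Nfatc4 was the 1 gene called (adjusted p = 0.0433) and the other 28 named genes past the threshold had adjusted p between 0.0711 and 0.114. The count was also 1 with array weights, 1 in a fit to only the groups compared, 2, 1 and 1 without CD34+ replicates 1, 2 and 3, and 1195 and 224 without Gli1+ replicates 2 and 3. In simulated data with the measured spread of each group 29.3% of such calls were on unchanged genes, and the split was 106 higher and 82 lower with cyclic loess and 54 and 50 with the deposited log2 values.

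Genes that set Gli1+ cells apart from both other populations numbered 20 higher and 15 lower. The higher genes included Tgfb2, Prdm1, Sprr1b, Mycn, Btc, Lipn, Dnase1l2, Scgb1a1, Flvcr2 and Actr5, and the lower ones Proser3 and Cisd1. The calls of Dnase1l2 and Proser3 rest on 1 probe each. Against CD34+ cells the other kept probes gave -0.07 and 1.08 for Dnase1l2 and -0.70 for Proser3. Prdm1 had a mean level of 8.76 ± 0.62 (SD, n = 2) in Gli1+ cells, 6.30 ± 0.32 (n = 3) in CD34+ cells and 5.83 ± 0.20 (n = 3) in IFE cells, and Tgfb2 had 9.08 ± 0.28, 7.16 ± 0.34 and 6.83 ± 0.23. Another 3 genes, Fzd2, Il31ra and the calcium-binding protein gene S100a4 (the last chosen after its values were seen), were lower than in CD34+ cells and higher than in IFE cells, by -1.51 and 2.29 for S100a4. Both comparisons use the same Gli1+ arrays, which by itself makes their differences alike. Across genes these correlated at 0.535, against a mean of 0.831 in 100 simulations of unchanged groups with the measured spreads and 0.601 with equal spread. Their covariance was 0.292, above the means of 0.237 with the measured spreads and 0.114 with equal spread. The overlap in the simulations with the measured spreads was at most 3 higher and 3 lower genes. There limma called a mean of 1.82 and 1.36 genes per comparison, too few to gauge the overlap of lists of 136 and 206. The overlap of 35 fell to 0 with the replicate block, with array weights, in fits to only the groups compared, without any 1 of CD34+ replicates 1, 2 and 3 and without IFE replicate 2 or 3; it was 3 without IFE replicate 1, and 658 and 98 without Gli1+ replicates 2 and 3. It was 41 higher and 13 lower with cyclic loess, 31 and 8 with median centring and 29 and 0 with the deposited log2 values.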

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

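The tests of mixing with IFE cells, of suprabasal cells, of co-varying genes and of background correction were chosen only after the result was seen, and the others before. Of 891 probes that passed the detection filter but carry no gene name, limma called 8 in Gli1+ versus CD34+, 19 in Gli1+ versus IFE and 24 in CD34+ versus IFE. They are outside the report's comparisons.

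The 2 Gli1+ arrays were less alike (r = 0.82) than the replicates of the other groups, and Gli1+ replicate 3 lacked 946 probes detected on all 7 other arrays. If transcripts were lost while amplifying little RNA, dim genes may spread most. The spread between the Gli1+ arrays, over that of other replicate pairs, was 1.9, 2.02, 2.06 and 1.63 in 4 equal sets of genes from the dimmest to the brightest, a ratio of dimmest to brightest of 1.16, which stays open because the ranges of those 2 sets overlap (1.68 to 2.02 and 1.56 to 1.71). Other cells in 1 pool also stay open: the largest difference of replicate 3 minus replicate 2 among 4 marker lists was a median of -0.655 for 4 melanocyte genes, with an error of 0.324. That error is taken over the 4 genes, which are not independent replicates. How well the gate for viable α6 integrin-positive cells removed other cells was not tested. A difference between the pools shared by all populations would make samples of the same number deviate alike, and for the Gli1+ arrays these correlations across genes were -0.031 to 0.027, while a difference in the Gli1+ cells of 1 pool alone was not tested.

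Epidermal differentiation genes were higher in Gli1+ than in CD34+ cells. IFE cells mixed into the Gli1+ sort could not lift a gene above both other populations. Of the 24 genes, 18 lay above both, with a median excess of 0.52. The list was examined because it was higher than in CD34+ cells. The 31.7% of all genes that lay above both is therefore not a matched baseline. Mixing with IFE cells stays open because the excess on Gli1+ replicate 2, 0.236, is within 2 SE of 0. That SE is taken over the list's genes, which are not independent replicates. Suprabasal cells also stay open, and how well the α6 integrin gate removed them was not tested. The median of 7 abundant suprabasal transcripts over IFE was 0.65, but these belong to the same list, and their excess over the other 17 members was 0.157 ± 0.268. This SE is also taken over genes and not from the limma fit. Chance movement of co-varying genes also stays open (camera adjusted p = 0.157 with an estimated correlation), and expression by hedgehog-responding basal cells themselves was not tested.

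Gli1 was higher in the GFP-negative CD34+ cells than in IFE cells. The tables argue against background correction or scaling as the cause: the difference passed the threshold under all 5 other corrections and scalings, with 1.21 the lowest and 2.53 the highest log2 difference (adjusted p between 0.00364 and 0.0144). Gli1+ cells carried over into the CD34+ sort may contribute, and would have to make up 27.9%, 87.5% and 36.5% of the 3 CD34+ samples. At the lowest of these shares, 12 of 123 genes higher in Gli1+ than in IFE lay below the level it requires by over 2 SE (9.76%). This was more than the 2.5% expected under carry-over but short of the 10% set in advance to exclude it, which keeps carry-over open. The 2.5% may be too low, since the genes were picked as high on the same Gli1+ arrays that set the required level. CD34+ replicate 2, which would need 87.5%, correlated across genes at 0.936 and 0.945 with the other CD34+ arrays. With Gli1+ replicates 2 and 3 it correlated at 0.885 and 0.827. Gli1 expression in CD34+ cells whose GFP is too dim to sort stays open as untested.

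For the 458 genes past the threshold in CD34+ versus IFE, the 6 arrays make 10 splits of 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 458 and the highest of the others 0 (limma, with 1613 and 254 at an unadjusted p under 0.05).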

How the results depend on the processing

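None of the alternatives here was chosen after the result was seen. The count in Gli1+ versus CD34+ (136) became 217 with normexp and an offset of 50, 209 without background correction, 265 with the stricter detection filter, 221 with a trend and robust eBayes, and 1 each with the replicate block, array weights and only the groups compared. Gli1+ versus IFE (206) became 338 with the stricter filter, 67 with the block, 3 with array weights and 6 with only the groups compared. CD34+ versus IFE (458) became 887 with array weights and 820 with only the groups compared. The overlap of both Gli1+ comparisons (35) became 54 with cyclic loess, 76 with the stricter filter and 0 with the block, array weights or only the groups compared, where limma gave 1458, 884 and 1295 genes at an unadjusted p under 0.05 in Gli1+ versus CD34+. Under the other settings with all arrays each count stayed within 1.5 times its value. Leaving out each array of the groups compared in turn gave 1 to 1195, 39 to 1200, 189 to 254 and 0 to 658, in that order, where a lone Gli1+ array is assumed to vary like the other groups. The stricter filter tests fewer genes (6575); otherwise the cause was not tested. Array weights were 0.411 for each Gli1+ array and 1.1 to 1.63 for the others. The Gli1+ weights are equal by design, since 2 arrays lie equally far from their mean, so they do not compare these arrays. Of 1034 list results under alternatives, 988 kept direction and side of the threshold, 31 no longer passed and 15 newly passed; of 3267 for named genes, 2739, 468 and 58, and 2 reversed. Those were Dnase1l2 in Gli1+ versus CD34+, at -0.135 without Gli1+ replicate 2 and -0.012 without replicate 3, within a range of -0.135 to 3.08, because another probe becomes the brightest. Signal over background limits detection to 38.62% to 49.04% of probes per array. Smaller changes were rarely called, with smallest called log2 differences of 1.39, 1.33 and 1.06. Slides as a block were not run.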
